A study of Phalaenopsis equestris with 4 samples.

How the data were processed

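Total RNA of root, stem, leaf and flower was made into standard Illumina libraries, 1 per tissue, and sequenced on a HiSeq 1500, per the labels' protocols and the series' design text. The authors assembled the reads de novo with Trinity (r2013-02-25, contigs of at least 200 nucleotides) and annotated the assembled sequences by BLASTx at an e-value below 0.00001, per the series' design text. The submitters' processing notes also name edgeR and DESeq, without version or role. The mapper, the FPKM estimator, the length used in it and any filter on reads are not given in the sources used here. Because the contigs are assembled from these same reads, fragments of 1 gene can appear as several contigs and near-identical copies can collapse into 1.

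The 3 deposited tables hold FPKM values by the authors, per the file headers and the name of the table. One covers all 221878 contigs. The other 2 match gene models to contigs for heat shock proteins and R genes, with an e-value and an alignment bit score per match, deposited by the authors; the search program for these is not given in the sources used here. Their FPKM values were equal to those of the same contig in the table of all contigs in each row that names a contig; 1 heat shock model, HSP20_PEQU_02461, has no contig and no values. Columns were assigned to tissues by the tissue named in the header. The headers also carry prefixes: those of root and stem share the letter L, while leaf has PHA and flower fb. What these prefixes mean is not given in the sources used here.

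The sums of FPKM were 895717 in root, 684575 in stem, 7179830 in leaf and 695751 in flower, so the libraries do not share a total. FPKM values are not counts, and no count test was run. The relative value of 1 read was estimated from the 154716 Trinity genes with a single contig: the ratios of low values in stem and root peaked at those of small whole numbers of reads, and contigs within 0.02 log2 units of a ratio of stem to root reads of 2 to 3, 3 to 2, 3 to 4, 4 to 3, 3 to 5 or 5 to 3 gave the value of 1 root read, against which flower and leaf values were set. Over these 6 sets the number of reads at equal FPKM relative to root ran from 1.78 to 1.79 for flower and from 0.0604 to 0.0616 for leaf. On simulated reads for 221878 contigs made with depths of 1.6, 1.8 and 0.0625 for stem, flower and leaf, the procedure returned 1.61, 1.84 and 0.0643. This ratio is the relative depth only if FPKM was computed on library totals. The leaf sum is larger than such totals allow for full contig lengths of at least 200 nucleotides with each fragment counted once. Either the leaf values were not divided by the library total or another length or count was used. Sums of reads divided by length, which do not depend on that total, were 1.22 times root in stem, 1.39 in flower and 0.491 in leaf, or 0.118 in leaf without c157498. Over the 6426 contigs used, the value taken for 1 read had a median of 0.402 FPKM in root, 0.253 in stem, 6.57 in leaf and 0.225 in flower. Its range from the 10th to the 90th percentile was 0.222 to 2.65 in root and 3.62 to 43.3 in leaf. No upper limit on FPKM was set, so contigs at multiples of these read numbers can enter and raise these values. They may thus be too high, and the simulation did not check them. Contig lengths were not used here, so the reads of each contig and their counting intervals were not computed, and a contig at 0 is described only as listed at 0.

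Each tissue has 1 library, so no test across tissues was possible and no p-value is given; whether a library stands for its tissue cannot be checked. Rules of size were fixed before the data were examined: expressed, FPKM of at least 1; pairwise difference, at least 4-fold on FPKM + 1 among contigs with a mean FPKM of at least 1; tissue-preferential, FPKM of at least 5 and at least 5-fold above the next tissue on FPKM + 1. Fold changes on this scale understate the change of low contigs. For a gene list, each contig's log2(FPKM + 1) was taken relative to its mean over the 4 tissues, and the list's median in each tissue was given as a percentile among 10000 random lists of the same size, matched on mean expression in 20 bins. This describes these libraries and is not a test across plants. Percentiles were computed for 5 lists in 4 tissues. In simulated data over 86757 contigs, 13 of 13 lists of 15 contigs raised 4-fold in flower passed percentile 97.5, as did 0 of 13 unchanged lists, and the preferential rule returned 200 of 200 planted contigs among 221878. The simulated lists came from values shuffled across tissues within each contig. They do not show how lists with smaller shifts are placed, and 13 unchanged lists are too few to give an error rate.

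Of 17 gene lists fixed before the data were examined, the 15 that needed annotation (such as photosynthesis, floral MADS-box genes, anthocyanin synthesis, pollen, vascular, fungal and viral transcripts) were void, since no contig name or annotation was in the tables used here, and 0 PEQU identifiers were in the RefSeq gene table of the species. The heat shock and R gene tables were used as lists, and the study chose these lists. Counting each contig once, and the counts of contigs lowest in a tissue, were choices made after the tables were seen. Named contigs were, for each tissue, the 2 with the widest preferential margin and the 2 of highest FPKM; named genes of the 2 tables were at least the 6 of highest mean and the 6 of widest range. Alternatives were other thresholds, fold sizes and pseudocounts (0.1 and 5 in place of 1), no filter on low values, median-of-ratios factors, and, for pairwise and preferential counts, sums of all libraries set equal. Added after the data were seen were sums without the c157498 component, no leaf library, each gene model counted, isoforms summed per Trinity gene, a bit score of at least 500, FPKM of at least 10, sums set equal for list medians, every alternative for counts of list members, and the comparison of flower with root and stem in matched random lists. A contig at 0 in both root and stem was counted as lowest in root. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.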

Results

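RNA sequencing libraries were compared from 4 tissues of Phalaenopsis equestris, a butterfly orchid: root, stem, leaf and flower of 3-year-old plants, with 1 library per tissue. Expression was given as FPKM for 221878 de novo assembled contigs in 178677 Trinity genes. FPKM by its usual definition is fragments scaled to transcript length and to library size. A Trinity gene is a group of contigs that the assembler regards as isoforms of each other. A pair of smaller tables matched gene models of the orchid, with identifiers beginning PEQU, to contigs for heat shock proteins and for R genes, the usual short name of plant disease resistance genes. With no replicate of any tissue, no difference below has a replicate check or a p-value, and each comparison is between libraries, described by fixed rules of size. Totals of reads were not given in the tables used here. In Trinity genes of a single contig, ratios of low FPKM values between libraries peaked at those of small whole numbers of reads, and from these peaks a contig at equal FPKM had 1.59 times as many reads in stem as in root, 1.79 times in flower and 0.0612 times in leaf. These ratios are relative depths only if the values were divided by library totals, which the sources used here do not state. The summed leaf FPKM was too large for such a division over full contig lengths with each fragment counted once. The leaf ratio may therefore not be a depth. Over the 6426 contigs used, 1 read was estimated at a median of 6.57 FPKM in leaf and 0.402 in root. In stem and flower the medians were 0.253 and 0.225, so a low or zero value in leaf carries the least weight. These medians may be too high, since contigs at multiples of small read numbers could enter. The median leaf value above 0 was 4.53 FPKM. The smallest value above 0 was 0.128 FPKM in leaf, 0.007 in root, 0.006 in stem and 0.007 in flower.

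The first comparison asked which transcripts each tissue expressed. At FPKM 1 or more, 117027 contigs were expressed in root, 89271 in stem, 57311 in leaf and 40768 in flower, and 24591 in all 4 tissues. Contigs past this level in a single tissue numbered 47347 in root, 17880 in stem, 7932 in leaf and 5609 in flower, and a further 25377 were expressed in root and stem but in neither leaf nor flower. The order of the tissues depended on the threshold: at FPKM 5 or more the counts were 30671 in root, 21047 in stem, 29772 in leaf and 17114 in flower, and at FPKM 10 or more leaf, with 6866, had more single-tissue contigs than root, with 5106. At the median read values above, FPKM 10 would be 1.52 reads in leaf and 24.9 in root. These leaf counts may thus rest on few reads per contig. Of the values above 0, 90.8% in leaf were at least 1 FPKM, against 68.3% in root, 50.8% in stem and 35.1% in flower. A further 14806 contigs were listed at 0 in all 4 tissues.

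**Figure D1:**
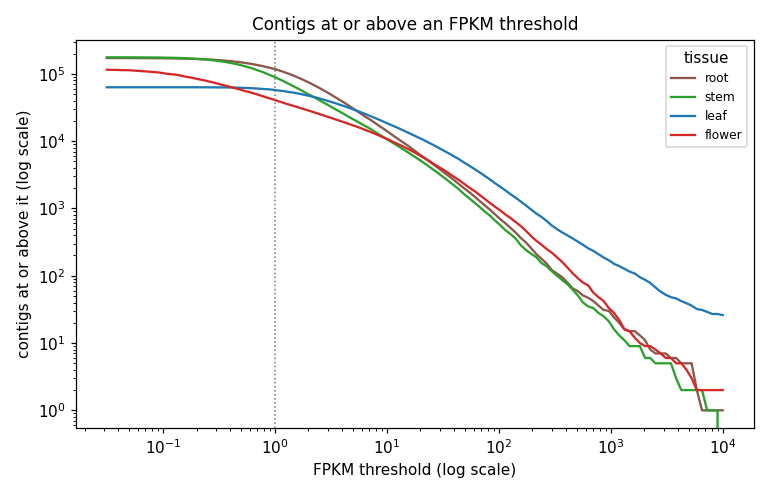
Number of contigs (y axis, log scale) at or above each FPKM threshold (x axis, log scale) in the 1 library of each tissue; the dotted line marks FPKM 1. At FPKM 1 root lies highest with 117027 contigs and flower lowest with 40768, while at high thresholds the leaf line lies above the rest.

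The most abundant transcripts differed in part between tissues. In leaf, 13 contigs of a single assembly component, c157498, held 75.9% of the summed FPKM, with values from 45292 to 895227 FPKM. The same 13 contigs were listed at 0 in root, reached at most 0.44 FPKM in stem, and lay between 66.4 and 1081 FPKM in flower, where they made up 0.978% of the sum. The files pair contigs with gene names only in the heat shock and R gene tables, so c157498 has no name here. In flower the highest contig was c118652_g1_i1 at 20372 FPKM, which stood at 0.261 FPKM in root and was listed at 0 in stem and leaf. Contig c29967_g1_i1 was the highest in both root, at 27425 FPKM, and stem, at 9099 FPKM, with 15917 FPKM in leaf and 970 FPKM in flower. Contig c155537_g1_i1 was the next highest in stem and in flower, with 6661 and 12196 FPKM, against 4039 in root and 1537 in leaf, and c139593_g1_i1 was the next highest in root, with 6368 FPKM there and 437, 1347 and 227 FPKM in stem, leaf and flower.

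A contig was called tissue-preferential where its highest tissue reached FPKM 5 and lay at least 5-fold above the next tissue on the FPKM + 1 scale. By this rule 4964 contigs were preferential in root, 3919 in leaf, 1110 in stem and 838 in flower, with median levels in their own tissue of 9.01, 22.0, 7.89 and 15.5 FPKM. Of the root-preferential contigs 3366 were listed at 0 in each of the remaining tissues, as were 869 of the stem-preferential, 290 of the leaf-preferential and 298 of the flower-preferential ones. The widest margins in root were those of c103978_g1_i1, at 366 FPKM against at most 0.969 elsewhere, and of c83156_g1_i1, at 107 FPKM and listed at 0 in the rest. In stem they were those of c100637_g1_i2, at 488 FPKM and listed at 0 in the rest, and of c146462_g1_i1, at 164 FPKM against at most 0.071. In leaf they belonged to c157498_g1_i1 and c157498_g11_i1, at 679228 and 318707 FPKM, and in flower to c118652_g1_i1 and to c118725_g1_i1, the latter at 1485 FPKM against at most 0.416. The counts depended on scaling between libraries: leaf had 1835 with median-of-ratios factors, and with the sums of all libraries set equal leaf had 221, stem 2382 and flower 1589. The flower count was 1275 without the leaf library. At the estimated median of 6.57 FPKM per leaf read, 1 leaf read against 0 would meet the rule, so the leaf count may rest on few reads. A leaf value of 0 likewise says little for root-preferential contigs, whose median in root was 9.01 FPKM.

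Each pair of tissues was then compared over the 86757 contigs with a mean FPKM of at least 1, counting differences of at least 4-fold on the FPKM + 1 scale. As deposited, stem and flower differed least, with 8321 contigs higher in stem and 2013 higher in flower, 11.9% of those compared. Root and stem followed at 15.2%, with 8995 higher in root and 4222 in stem, and leaf and flower at 19.6%, with 14492 higher in leaf and 2502 in flower. Stem and leaf differed at 21.2%, with 9200 contigs higher in stem and 9212 in leaf. Root stood furthest apart, at 35.5% from flower, with 26013 higher in root and 4809 in flower, and at 41.0% from leaf, with 23861 higher in root and 11680 in leaf. At the estimated median of 6.57 FPKM per leaf read, a single leaf read against 0 would already pass the 4-fold rule. The comparisons with leaf can therefore rest on few reads. With a pseudocount of 5 the larger side turned for root and leaf, with 2151 higher in root and 4215 in leaf, and for stem and flower, with 609 higher in stem and 657 in flower. Which pair differed least depended on the rule. Root and stem did at 2-fold (34423 contigs, against 35874 for stem and flower), with a pseudocount of 0.1 (23986 against 38025) and with sums set equal (13793 against 15102), and leaf and flower did with median-of-ratios factors (11629 against 12003). Pearson's r of log2(FPKM + 1) across contigs, which are not independent replicates, ran from 0.26 for root and leaf and 0.36 for root and flower through 0.53 for root and stem, 0.57 for stem and leaf and 0.69 for leaf and flower to 0.71 for stem and flower. The Spearman's rho values in the same order were 0.06, 0.12, 0.36, 0.41, 0.60 and 0.56. Over the 24591 contigs expressed in all 4 tissues r was 0.68, 0.63, 0.82, 0.80, 0.77 and 0.81, so that root and stem were then the most alike pair.

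The balance of the leaf comparisons depended on scaling. Median-of-ratios factors over contigs above FPKM 1 in all 4 tissues placed the deposited leaf values 0.87 log2 units above root, 0.83 above stem and 0.82 above flower. If 1 leaf read is worth the estimated median of 6.57 FPKM, contigs of low level enter only where leaf had a read. The filter may thus itself raise the leaf factor, which was not tested. Of the 4-fold differences, the share higher in leaf than in root was 32.9% as deposited, 19.5% with these factors and 3.38% with sums set equal. For stem and leaf the counts were nearly equal as deposited, and the share higher in leaf was 29.4% and 2.27% with the other scalings. For leaf and flower the share higher in flower was 14.7%, 28.7% and 93.8%, so the direction flipped in the last setting, in which c157498 takes most of the leaf total.

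The heat shock protein table asked how the chaperones that handle unfolded proteins were expressed across tissues. It listed 29 gene models, 28 of them with a contig, on 27 contigs: 13 of HSP20, the small heat shock proteins, 8 of HSP70 and 6 of HSP90. Of all 27 contigs 15 were highest in flower, 12 in leaf and none in root or stem, and 18 were lowest in root, 1 of them tied with stem at 0. The 12 in leaf compare with a mean of 16.6 in matched random lists, and were 4 with median-of-ratios factors and 0 with sums set equal, while the count in flower was 21 and 22. With sums set equal only 4 contigs were lowest in root, the same tie included, and 2 were highest in root and 3 in stem. HSP20 was the family with the most marked tissue pattern. Of its 13 contigs, 11 were highest in flower and 13 were higher in flower than in both root and stem, with a median of 53.9 FPKM in flower against 2.40 in root, 7.31 in stem and 7.69 in leaf. On the log2(FPKM + 1) scale the median difference between flower and root was 2.93, and it reached at least 4-fold in 9 contigs. The count highest in flower was 12 of 13 with median-of-ratios factors and 13 of 13 with sums set equal. Set against 10000 random lists of contigs matched on mean expression, the HSP20 median in flower, 1.67 log2 units above each contig's own mean, lay at percentile 100, and the median in root, at -1.07, lay at percentile 0.23. The medians in stem, at -0.47, and in leaf, at 0.06, lay at percentiles 1.59 and 1.46, but inside the central 95% in some alternatives, at up to 7.16 for stem with a bit score of at least 500 and 5.95 for leaf with each gene model counted.

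Single HSP20 genes differed widely in range. HSP20_PEQU_14369 was at 391 FPKM in flower, 2.40 in root, 7.31 in stem and 0.862 in leaf, the widest range in the table at 7.72 log2 units. HSP20_PEQU_14367 was at 72.6 FPKM in flower and 0.782 in root, with 9.22 in stem and 19.6 in leaf. HSP20_PEQU_23676 was at 122 FPKM in flower and between 3.08 and 7.69 elsewhere, HSP20_PEQU_14371 at 53.9 in flower and 2.29 in root, and HSP20_PEQU_07221 at 52.1 in flower, 10.1 in root, 13.3 in stem and 2.20 in leaf. HSP20_PEQU_09331 was the most abundant of the family by mean, with 246 FPKM in flower, 151 in leaf, 68.3 in stem and 23.5 in root. HSP20_PEQU_10259 and HSP20_PEQU_14374 varied least, by 1.37 and 1.31 log2 units, with 76.5 and 89.1 FPKM in flower. HSP20_PEQU_08607 and HSP20_PEQU_09328 reached 19.6 and 36.9 FPKM in flower against 2.17 and 2.60 in root. The exceptions were HSP20_PEQU_07627, low everywhere and highest in leaf at 3.99 FPKM, and HSP20_PEQU_23675, at 39.6 FPKM in leaf, 6.61 in flower and listed at 0 in root and stem. Both leaf values lay within 3.62 to 43.3 FPKM, the 10th to 90th percentile of the estimated value of 1 leaf read, so both may rest on few reads. The same limit holds for low leaf values of contigs highest in flower, such as those of HSP20_PEQU_14369 and HSP20_PEQU_07221. The contig given for HSP20_PEQU_23675 had a bit score of 126, the weakest match in the table, so its identity is uncertain. HSP20_PEQU_17855 and HSP20_PEQU_41347 were assigned the same contig, at 2.54 FPKM in flower, and were counted once.

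**Figure D2:**
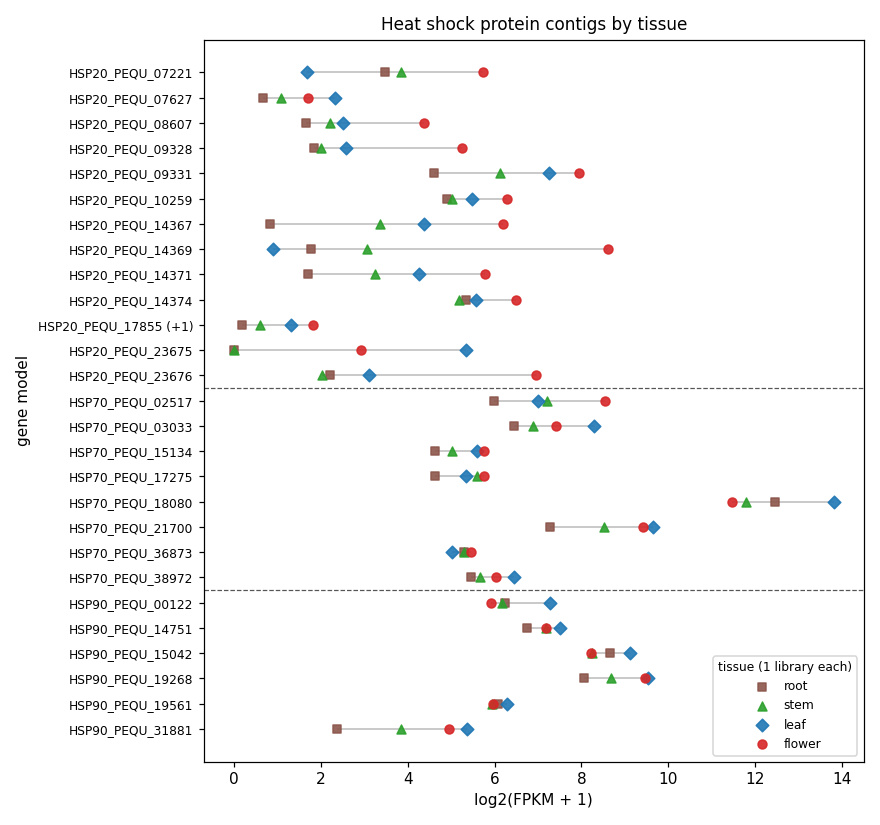
Expression as log2(FPKM + 1) (x axis) of the 27 heat shock protein contigs (y axis, by gene model; +1 marks a second model on the same contig) in root, stem, leaf and flower, 1 library each, with grey lines from the lowest to the highest tissue and dashed lines between HSP20, HSP70 and HSP90. Flower is the highest tissue for 11 of 13 HSP20 contigs, and leaf for 6 of 6 HSP90 contigs at the deposited scaling.

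HSP70 and HSP90 contigs varied less, with median ranges of 1.48 and 1.13 log2 units against 3.40 for HSP20, and all but HSP90_PEQU_31881 were at 23.7 FPKM or more in each tissue. The 8 HSP70 contigs had medians of 117 FPKM in flower, 106 in leaf, 83.8 in stem and 52.9 in root, with 4 highest in flower, 4 in leaf and 6 lowest in root as deposited. The count highest in leaf was 2 with median-of-ratios factors and 0 with sums set equal, the count lowest in root was 5 and 0, and the count highest in flower was 6 and 7. Flower was above both root and stem in 7 of 8 contigs as deposited and in both of these scalings. Matched random lists had a mean of 4.04 such contigs as deposited, and 3.67% of lists had as many. HSP70_PEQU_18080 had the highest mean FPKM in the table, with 14278 FPKM in leaf, 5644 in root, 3516 in stem and 2829 in flower, and its contig ranked 23rd, 3rd, 4th and 7th among all contigs of those libraries. HSP70_PEQU_02517 was at 372 FPKM in flower against 62.9 in root, HSP70_PEQU_21700 at 794 in leaf and 682 in flower against 154 in root, and HSP70_PEQU_03033 at 312 in leaf against 86.8 in root. HSP70_PEQU_36873 ranged only from 31.6 to 42.7 FPKM. The 6 HSP90 contigs were all highest in leaf as deposited, with a median of 167 FPKM there against 90.4 in root, but only 1 of 6 was highest in leaf with median-of-ratios factors and 0 with sums set equal. HSP90_PEQU_19268 was at 742 FPKM in leaf, 706 in flower, 408 in stem and 266 in root, HSP90_PEQU_15042 at 551 in leaf and between 297 and 401 elsewhere, and HSP90_PEQU_31881 at 39.9 in leaf, 30.0 in flower, 13.4 in stem and 4.19 in root. The medians of HSP70 and HSP90 lay between percentiles 11.1 and 89.4 of matched random lists in all 4 tissues, and none was outside the central 95%.

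The R gene table listed 35 gene models, but these fell on only 17 contigs. A single contig, c157580_g2_i2, stood for 16 of the models, among them PEQU_01621, PEQU_18351 and PEQU_41490, and its values of 29.2 FPKM in leaf, 17.6 in stem, 13.1 in root and 11.5 in flower cannot be divided among them. Each contig was therefore counted once. R gene contigs were low in flower: 16 of 17 were lowest there, and 17 of 17 were lower in flower than in both root and stem, with medians of 2.29 FPKM in flower, 8.89 in root, 8.51 in stem and 10.7 in leaf. The median difference between flower and root was -1.17 on the log2(FPKM + 1) scale, and 11 of 17 contigs were at least 2-fold lower in flower. The same median was -1.07 over all 86757 contigs and -0.20 over matched random lists, among which the R genes lay at percentile 3.18, inside the central 95%. Against stem the median difference was -1.08, at percentile 0.67, outside the central 95%. In matched random lists a mean of 7.88 contigs were lower in flower than in both root and stem, and 0% of lists had 17. The count lowest in flower was 15 of 17 with median-of-ratios factors but 1 with sums set equal, where leaf became the lowest tissue for the rest and 15 of 17 remained lower in flower than in both root and stem. The flower median, -0.96 log2 units from each contig's own mean, lay at percentile 1.38 of matched random lists, but at 3.55 with isoforms summed and 3.04 with each gene model counted, inside the central 95%. Leaf was the highest tissue for 11 of 17 contigs as deposited and for 5 with median-of-ratios factors, and its median lay at percentile 70.8, with root and stem at 89.5 and 97.1. The stem value lay outside the central 95% in 3 alternatives, at up to 99.8 with each gene model counted, where root was at 45.6.

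The tissue in which an R gene contig was highest also depended on scaling. PEQU_27349 was the most abundant, at 118 FPKM in leaf, 84.7 in root, 50.4 in stem and 23.4 in flower, followed by PEQU_12877, at 64.6 in leaf and 13.7 in flower. PEQU_36285 and PEQU_38720, on 1 contig, were at 48.4 FPKM in leaf and 9.29 in flower, and PEQU_22921 at 10.7 in leaf against 1.43 to 2.35 elsewhere. PEQU_41464 had the widest range, 4.01 log2 units, with 27.7 FPKM in leaf, 21.9 in root, 17.8 in stem and 0.778 in flower. Root was the highest tissue for 4 contigs as deposited, for 8 with median-of-ratios factors and for 8 with sums set equal. PEQU_18392 was at 49.4 FPKM in root, 34.7 in stem, 25.3 in leaf and 5.72 in flower, and PEQU_35950 with PEQU_35952, on 1 contig, was at 22.7, 8.65, 4.21 and 1.84. PEQU_23626 was at 5.00 FPKM in root, 2.09 in stem, 0.16 in leaf and 0.149 in flower. PEQU_15333 was at 4.32 FPKM in root, 1.09 in flower and 0.766 in leaf, the one contig that was not lowest in flower as deposited. That leaf value was below the estimated median value of 1 leaf read, 6.57 FPKM, so this order may rest on few reads. The same limit holds for PEQU_23626, counted as lowest in flower, whose leaf and flower values were nearly equal at 0.16 and 0.149 FPKM. As deposited, stem was the highest tissue for PEQU_03884 and PEQU_15036, at 3.88 and 4.29 FPKM, and it was highest for 4 and 9 contigs in the same scalings.

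**Figure D3:**
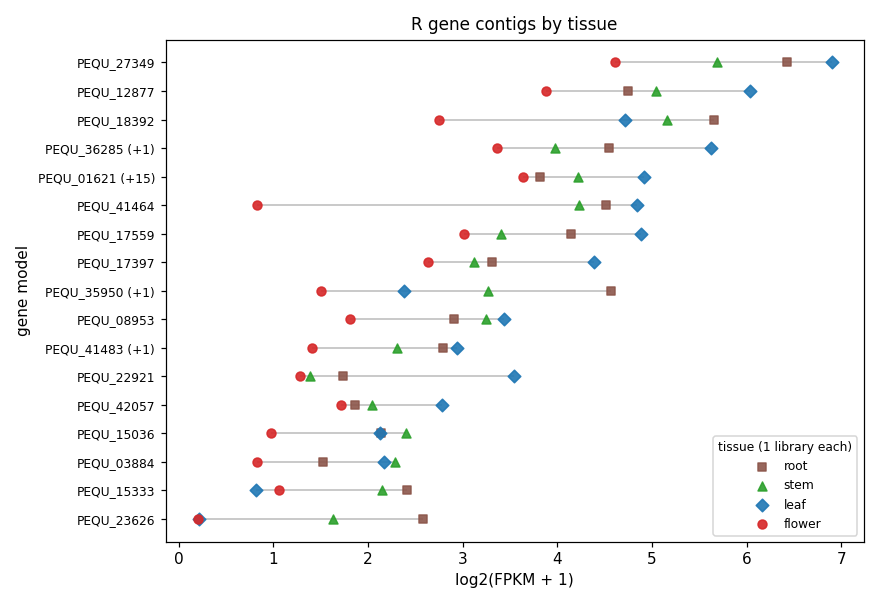
Expression as log2(FPKM + 1) (x axis) of the 17 R gene contigs (y axis, by gene model in order of mean FPKM; a number after + counts the further models on the same contig) in root, stem, leaf and flower, 1 library each, with grey lines from the lowest to the highest tissue. Flower is the lowest tissue for 16 of 17 contigs as deposited, and c157580_g2_i2, shown as PEQU_01621, carries 15 further models.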

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

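The alternatives chosen after the data were seen were sums without the c157498 component, no leaf library, each gene model counted, isoforms summed per Trinity gene, a bit score of at least 500, FPKM 10, sums set equal for list medians, and every alternative for counts of list members. With 1 library per tissue there were no replicates to leave out. No paired analysis was possible because each tissue has 1 library. A count is treated as moved when it differs by more than 1.5 times, a list median when it leaves the 95% bootstrap interval over its contigs, and a correlation when it leaves its 95% interval over contigs; the cause was not tested unless the setting itself shows it. Among counts of list members 70 did not move and 17 did. Among list medians 119 stayed within the interval, 34 moved, and a further 7, outside the central 95% as deposited, were reversed. Counted over all 160 medians, 26 changed sign, 25 of these under the 3 scalings of the libraries. Some of the 26 stayed within the interval. The large estimated value of 1 leaf read limits low leaf values the most. The 3 scalings of the libraries, which each change all 4 tissues, moved the most list results. The flower results of HSP20 kept their direction in each alternative.

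For expressed contigs, FPKM 0.5 gave 134214 in stem, and FPKM 5 gave 30671 in root, 21047 in stem, 29772 in leaf, 17114 in flower and 10110 in all 4 tissues. Single-tissue contigs were 2460 in leaf at FPKM 0.5, then 13653 in root, 2599 in stem and 1804 in flower at FPKM 5, and 5106, 820 and 1273 at FPKM 10. Tissue-preferential contigs in root, stem, leaf and flower were 12539, 2102, 12299 and 1918 at a 2-fold margin and 1516, 262, 1379 and 380 at a 10-fold margin. Median-of-ratios factors gave 1835 in leaf. Sums set equal gave 2382 in stem, 221 in leaf and 1589 in flower, and without c157498 in the sum these were 2295, 1388 and 1376. Without the leaf library 1275 were preferential in flower.

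For pairs of tissues, a 2-fold rule gave 24015 contigs higher in root than stem and 10408 the other way, 24421 higher in leaf than root, 44515 higher in root than flower and 10972 the other way, 23395 higher in stem than leaf and 23700 the other way, 29764 higher in stem than flower and 6110 the other way, and 30540 higher in leaf than flower and 6289 the other way. In the same form an 8-fold rule gave 2682 and 1340 for root and stem, 7611 and 4920 for root and leaf, 7832 and 2013 for root and flower, 2299 and 3258 for stem and leaf, 1839 and 753 for stem and flower, and 5374 and 1011 for leaf and flower. A pseudocount of 0.1 gave 15294 and 8692 for root and stem, 42966 and 8853 for root and flower, 26722 and 14280 for stem and leaf, 34014 and 4011 for stem and flower, and 24662 and 10517 for leaf and flower. A pseudocount of 5 gave 970 and 583 for root and stem, 2151 and 4215 for root and leaf, 2702 and 1613 for root and flower, 514 and 3088 for stem and leaf, 609 and 657 for stem and flower, and 3530 and 576 for leaf and flower, so the larger side changed for root and leaf and for stem and flower. Median-of-ratios factors gave 6652 higher in leaf than root, 4727 higher in leaf than stem and 8286 higher in leaf than flower. Sums set equal gave 36349 and 1272 for root and leaf, 27767 and 645 for stem and leaf, 12820 higher in stem than flower, and 1009 and 15296 for leaf and flower. Without c157498 in the sum there were 6035 higher in leaf than root, 15189 and 3399 for stem and leaf, 12786 higher in stem than flower, and 6589 and 4687 for leaf and flower. Pearson's r for root and stem, root and leaf, root and flower, stem and leaf, stem and flower, and leaf and flower was 0.35, 0.10, 0.20, 0.44, 0.60 and 0.63 at a pseudocount of 0.1, and 0.61, 0.49, 0.47, 0.68, 0.72 and 0.75 with no filter.

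For the lists, medians are log2 units from each contig's own mean. A pseudocount of 0.1 gave -1.24 for R genes in flower. Median-of-ratios factors gave in leaf 0.17 for R genes, -0.071 for all heat shock proteins, -0.55 for HSP20, -0.17 for HSP70 and -0.048 for HSP90, and in stem -0.13 for all heat shock proteins and -0.28 for HSP20; leaf was then highest for 5 R gene, 2 HSP70 and 1 HSP90 contigs. Sums without c157498 gave for R genes 0.55 in stem, -0.093 in leaf and -0.67 in flower, for all heat shock proteins 0.075 in stem and -0.35 in leaf, for HSP20 -0.11 and -0.82, for HSP70 0.22, -0.44 and, in flower, 0.72, and for HSP90 0.19 in stem and -0.32 in leaf; leaf was then highest for 3 R gene, 1 HSP70 and 0 HSP90 contigs. Sums with c157498 gave for R genes 0.93 in stem, -1.18 in leaf and -0.35 in flower. They gave in root, stem, leaf and flower -0.32, 0.57, -1.83 and 1.63 for all heat shock proteins, -0.76, 0.19, -1.78 and 2.38 for HSP20, -0.14, 0.72, -1.88 and 1.18 for HSP70, and 0.27, 0.70, -1.85 and 0.86 for HSP90. In that setting leaf was highest for 0 R gene, 0 HSP70 and 0 HSP90 contigs, 1 R gene contig was lowest in flower, and root was lowest for 4 heat shock contigs in all, 3 of HSP20, 0 of HSP70 and 1 of HSP90, with HSP20_PEQU_23675, at 0 in both root and stem, counted under root. The leaf medians of all heat shock proteins and of HSP20 thus changed sign under each of these scalings, and the HSP20 stem median under the last. The leaf medians of HSP70 and HSP90 also lay below 0 in all 3 scalings, and that of R genes in the scalings by sums. The flower median of HSP90, close to 0 as deposited, was 0.15 with median-of-ratios factors and 0.38 with sums without c157498. Counting each R gene model gave -0.24 in root and -0.55 in flower, with 28 of 35 highest in leaf and 34 lowest in flower, since 16 models share a contig. Without the leaf library 23 of 27 heat shock contigs were highest in flower.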

Other observations

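The tests of explanations in this part were chosen after the result was seen, except the question of foreign RNA in root, as were the counts of contigs lowest in a tissue; list medians, their percentiles and counts of contigs highest in a tissue were fixed before. The table of R gene models held few separate measurements: 22 of its 35 models lay on 4 shared contigs, against 2 of 28 heat shock models with a contig on 1 shared contig. HSP90_PEQU_19561 was the steadiest member of the heat shock table, between 60.9 and 77.5 FPKM, and HSP70_PEQU_36873 the next, while HSP90_PEQU_31881 was the HSP90 contig of widest range, at 2.98 log2 units. HSP70_PEQU_38972, HSP70_PEQU_15134 and HSP70_PEQU_17275 were at 42.8, 23.7 and 23.8 FPKM in root, the lowest tissue for each, and at 64.3, 52.8 and 53.0 FPKM in flower. Among the R genes, PEQU_42057 had the highest bit score, 6282, and stayed between 2.29 and 5.87 FPKM in all 4 tissues.

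The HSP20 contigs were highest in flower in 11 of 13 cases. A library-wide scaling of the authors' values would move random contigs alike, and the HSP20 flower median lay at percentile 100 of matched lists, which argues against scaling as the whole cause. Flower was above root and stem in 13 of 13 contigs, comparisons that leaf does not enter. Whether few reads in leaf shaped the comparison of flower with leaf stays open. Only 4 contigs were at or above 32.8 FPKM in leaf, the value of 5 reads at the median read value, and 3 of these were higher in flower. That limit appears too high for some HSP20 contigs, since HSP20_PEQU_14369 was at 0.862 FPKM in leaf and HSP20_PEQU_07221 at 2.20. The reads behind each leaf value are not known, so this count cannot decide the question. A heat or stress state of this flower sample at harvest may have contributed: it would be expected to raise HSP90 as well, whose flower median lay at percentile 54.0. HSP70 leaned the other way, with 4 of 8 contigs highest in flower against a mean of 1.25 in matched random lists and a flower median at percentile 89.4. With so few contigs and 1 library the question stays open. A difference between tissues in HSP20 expression is the biological explanation that the design names, and it remains a hypothesis untested without a second flower sample.

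The R gene contigs were lowest in flower in 16 of 17 cases with each contig counted once. At equal FPKM flower had 1.79 times the reads of root, and its sum of reads divided by length was 1.39 times that of root, which argues against a loss of reads in a shallower library. A library-wide scaling would move matched random contigs alike. Flower was below both root and stem in 17 of 17 contigs, against a mean of 7.88 in matched random lists. Of those lists 0% had as many. The count was 17 with median-of-ratios factors and 15 with sums set equal. The count was thus far above that of lists matched on mean level. Median-of-ratios factors were nearly alike in root, stem and flower, at 0.846, 0.869 and 0.870, so keeping the count under them says little. The random lists were not matched on spread between tissues, so the count cannot decide whether scaling made this direction. Scaling also stays open for the size of the difference from root, at percentile 3.18, and for the rank of flower against leaf. The flower median lay at percentile 1.38 of matched lists, but over the 8 alternatives it ran from percentile 0.24 to 3.55, passing 2.5 when isoforms were summed (3.55) or each model was counted (3.04). Under scaling the flower median lay at percentile 1.54 with median-of-ratios factors, 1.70 with sums set equal and 1.23 with sums without c157498. With 20 percentiles computed, the standing of this list among random ones is weaker than that of HSP20. With sums set equal only 1 contig was lowest in flower, because leaf became the lowest tissue for 16. A lower level of R gene transcripts in flower may be a property of the tissue, which these libraries cannot separate from a property of the 1 flower sample.

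Contigs expressed in root only were 2.65 times as many as those in stem only at FPKM 1. If values of few reads near the threshold made this excess, it would be expected to shrink at higher levels, and at FPKM 10 the ratio was 6.23. The threshold was the same in all tissues, so a root-only contig at FPKM 10 may lie just below 10 elsewhere. The sets at FPKM 1 and 10 thus differ, and the ratio cannot decide the question. Against flower the excess shrank, from 47347 root-only and 5609 flower-only contigs at FPKM 1 to 5106 and 1273 at FPKM 10. The ratio against leaf, 5.97 at FPKM 1 and 0.744 at FPKM 10, cannot decide it either, since 1 leaf read was estimated at a median of 6.57 FPKM. RNA of another organism on or in the root, such as a fungal partner, is a candidate source of some of the 5106 contigs at FPKM 10 or more in root and below 10 elsewhere. It cannot be told apart from root genes of the orchid here because no sequence or annotation of these contigs was searched.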
